A study of Mus musculus with 6 samples.

How the data were processed

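Droplet-based (10x Chromium) RNA sequencing was done on cells of the preoptic region of Mus musculus, dissociated with protease and sorted for live cells, in 3 female and 3 male libraries, each a pool of 3 mice aged 60 to 70 days. The authors deposited raw UMI counts (counts of unique molecular identifiers per gene and cell) in 1 table for all libraries, with the library of each cell given by the number that ends its barcode. Per the submitters' processing notes, Cell Ranger 2.0.0 and mouse build mm10 were used. The gene annotation, the strand of counting, the rule that called cells and the chemistry version are not given in the sources used here. All deposited values were checked to be whole numbers, and the authors' cell annotation is not among the files, so classes were rebuilt and a difference from the study's own classes may come from that. Genes were matched by Ensembl ID to the GENCODE annotation of the same build, where 90 of 90 genes named in the texts were found. The table held 56 duplicated gene symbols.

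Cells with fewer than 500 genes or over 20% mitochondrial counts were left out (475 barcodes), then doublets called by Scrublet in each library at an expected rate of 0.06 (1113 barcodes, 3.61% of the rest), which left 29711 cells: 4532, 9336 and 406 in female replicates 1, 2 and 3 and 6998, 6500 and 1939 in male replicates 1, 2 and 3. Counts were scaled to 10000 per cell and logged. Clusters came from 2000 variable genes (library as batch, genes of the outcome lists left out), 30 principal components, 15 nearest neighbours and Leiden at resolution 1.0, with seed 0. A cluster was neuronal with at least 8 neuronal markers in 50% of its cells. It was named inhibitory with Gad1, Gad2 and Slc32a1 each in at least 50% and Slc17a6 in under 25% of cells, and excitatory with Slc17a6 in at least 50% and Slc32a1 in under 25%. Other clusters took the class with the largest share of its markers over 1 log2 unit above the remaining cells and in at least 10% of cells, and excitatory clusters and these needed 3 such markers. A name was withdrawn where more of the 10 leading genes were markers of another class than of the class named. Clusters 0 and 16 lost the name inhibitory neuron in this way, by 1 gene each. Neurons were clustered again on their own at resolution 1.5. Tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

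UMIs were summed per library over all cells or over the cells of a class, and values are given as UMIs per 1000000 UMIs of that sum (CPM). Female was compared with male by the edgeR quasi-likelihood test with TMM scaling and its default expression filter (minimum count 10), in all cells and in each class with at least 20 cells in each library. Differences are female minus male in log2, and the standard error is the log2 change divided by the root of the F statistic. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05. Inhibitory and excitatory neurons were compared with the library as block, and the sex difference was compared between them by an interaction term. In that model the variation within a library is shared between all libraries, which makes its p-values small for genes that differ between pools. Class shares were compared by exact two-sided permutation and numbers of neurons per cluster by edgeR with the neurons of a library as its size. Listed genes were compared across classes by exact two-sided sign flips of 6 paired log2 differences (pseudocount 1), whose smallest p is 0.03125. For the log2 ratios of inhibitory to excitatory neurons and the list medians per library, a prior count of 2 was used. A fold against libraries that all held 0 UMIs is a lower bound computed from a floor of 3 UMIs over the group, which covers counting error only.

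The 18 fixed lists were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, on voom weights: Y-linked genes, X-inactivation transcripts and X genes that escape it, steroid receptors and steroid-converting enzymes, peptide receptors, neuropeptides, monoamine, acetylcholine and nitric oxide genes, genes reported as sexually dimorphic in the rodent hypothalamus, early response and dissociation genes, mitochondrially encoded genes, interferon response genes, MHC class I genes, cholesterol synthesis genes, glucocorticoid-responsive genes, clock genes, GABA-A and glycine receptor subunits, glutamate receptor subunits, patterning transcription factors and hemoglobin genes. The lists, marker lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule took, for sex, all tested Y and X list genes, up to 10 called genes per direction that separated the libraries and up to 3 members per list with the smallest p. For inhibitory against excitatory neurons it took up to 4 called genes per list and direction with at least 10 CPM in either class and 1 direction in all 6 libraries, across classes the 6 with the largest ratio per list with at least 20 CPM together with Esr1, Pgr, Cyp19a1, Prlr, Gal and Th, and the 3 neuronal clusters with the smallest p. The 8 genes named of the 34 called for the interaction were chosen after their values were seen.

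Alternatives were DESeq2, RLE and total-count scaling, no filter or a minimum count of 50, doublets kept, stricter cells (1000 genes, 10% mitochondrial counts), cells thinned to 1500 UMIs, Leiden resolution 2.0, classes set by transmitter UMIs, the replicate number as a block, and each library left out in turn. For inhibitory against excitatory neurons no library block was also tried, and for class shares edgeR on cell numbers with and without the replicate block. Cluster sizes were also tested at Leiden resolutions 1.0 and 2.5, without genes called between the sexes among the variable genes, with TMM and by exact permutation. Chosen after seeing the data were the comparisons of 5 classes without female replicate 3, the edgeR tests across classes, inhibitory neurons without the cluster led by Avp, the thinned and left-out medians of the glucocorticoid list and the swaps of sex within replicate numbers. In female replicate 3, whose 1278429 UMIs are the fewest of the 6 libraries, 4 excitatory neurons, 4 cells of cluster 16, 13 microglia, 5 mural cells and 6 newly formed oligodendrocytes were kept. On simulated counts with the depths and dispersions of these data, edgeR found 82% of genes changed 2-fold in all cells, 97% in inhibitory neurons, 18% in astrocytes and 24% in endothelial cells, and at least 86% of genes changed 4-fold in each of these. Genes were simulated independently of each other, and the changed ones were not drawn from the lowest expressed, so the share found in real data may be lower. Ependymal cells, tanycytes, lymphocytes, monocytes, choroid plexus and pituitary cells had marker lists but no cluster. Macrophages, fibroblasts, dividing cells and clusters 21 and 25 had too few cells for a comparison of genes. Results of some genes that the rule takes in are not reported here.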

Results

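RNA of single cells was profiled from the preoptic region of the hypothalamus, a brain area that takes part in social and parental behaviour, sleep, thirst and body temperature in adult mice of both sexes. Each of 6 libraries came from a pool of 3 mice aged 60 to 70 days that had lived alone for 3 days. Of these, 3 were female and 3 male. The labels state separate pools, so the library, not the cell, was the replicate. The deposited table held 27998 genes, 31299 cell barcodes and 217266089 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule). Female replicates 1, 2 and 3 held 33230552, 81162330 and 1278429 UMIs in 4715, 9845 and 451 barcodes. Male replicates 1, 2 and 3 held 45331338, 47403686 and 8859754 UMIs in 7385, 6899 and 2004 barcodes. The median barcode held 5797, 6689 and 2332 UMIs in the female and 4946, 5506 and 3561 UMIs in the male libraries. Female replicate 3 was the smallest library and kept 406 of the 29711 cells that passed the filters.

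The cells fell into 27 clusters, which were given class names from marker lists fixed beforehand, so each name stands for a marker profile. Inhibitory-like neurons (Gad1, Gad2 and Slc32a1, which make and load GABA) were the largest class with 11323 cells. Excitatory-like neurons (Slc17a6, the vesicular glutamate transporter) held 3193. The oligodendrocyte lineage, which makes myelin, was split into 6637 mature oligodendrocytes, 409 newly formed oligodendrocytes and 1558 oligodendrocyte precursors. Microglia held 792 cells, astrocytes 785, endothelial cells 476, mural cells 446, dividing cells 116, macrophages 74 and fibroblasts 64. Of the 4 clusters left without a name, clusters 0 and 16 also carried inhibitory transmitter genes, with Gad1 in 81.9% and 96.3% and Slc17a6 in 2.8% and 4.3% of cells. They were kept apart from the inhibitory neurons because 1 of the 10 leading genes of each is on the marker list of another class and none is on that of inhibitory neurons. Cluster 0 (3047 cells) was led by Ppp1r1b, Arpp21, Adora2a and Penk, genes known from striatal projection neurons. Cluster 16 (563 cells) was led by Igfbp4, Slc10a4, Moxd1, Crabp1 and Slc5a7, the choline transporter. Cluster 25 (142 cells) was led by Rrad, Gem, Gal and Fosb, and 97 of its cells came from female replicate 2. Cluster 21 (86 cells) carried astrocyte markers. Among the microglia, cluster 11 was led by Ccl3, Ccl4, Cd14 and Il1a, inflammatory genes. Free RNA was measurable. Snap25, a synaptic gene, had a UMI in 97.0% of inhibitory neurons (median depth 6899 UMIs) and in 36.0% of mature oligodendrocytes (median depth 4826 UMIs), which should lack it. The share in mature oligodendrocytes differed between the pools, at 29.3, 51.8 and 1.47% in female and 35.25, 30.7 and 20.4% in male replicates 1, 2 and 3.

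The shares of the classes were compared to ask whether females and males differ in cell composition. Newly formed oligodendrocytes made up 1.10 ± 0.349% of cells in female and 1.85 ± 0.264% in male libraries (SD, n = 3 each), with all 3 female values below all 3 male values. Macrophages went the other way, at 0.524 ± 0.400% against 0.172 ± 0.0637%, with a female mean of 0.294% without female replicate 3, where 4 cells made 0.985%. Inhibitory neurons stood at 34.1 ± 13.7% and 33.9 ± 3.77% and excitatory neurons at 8.38 ± 6.52% and 8.69 ± 2.39%. Mature oligodendrocytes were at 24.2 ± 8.11% and 25.4 ± 7.21% and cluster 0 at 9.45 ± 1.74% and 11.7 ± 2.01%. Female replicate 3 stood apart: inhibitory neurons were 18.2% of its cells, excitatory neurons 0.985%, oligodendrocyte precursors 13.1%, astrocytes 9.61% and endothelial cells 6.65%. Without it the female means were 42.0%, 12.1%, 4.44%, 2.20% and 1.64%. None of the 16 classes differed. An exact two-sided permutation test, which cannot go below 0.1 with 3 libraries against 3, gave p = 0.1 for newly formed oligodendrocytes and for macrophages. It put 0 classes under an unadjusted 0.05, with adjusted p = 0.8 at the smallest. edgeR on the cell numbers also called 0 classes, with 1 under an unadjusted 0.05, newly formed oligodendrocytes at -0.86 ± 0.35 on the log2 scale (adjusted p = 0.630).

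**Figure D1:**
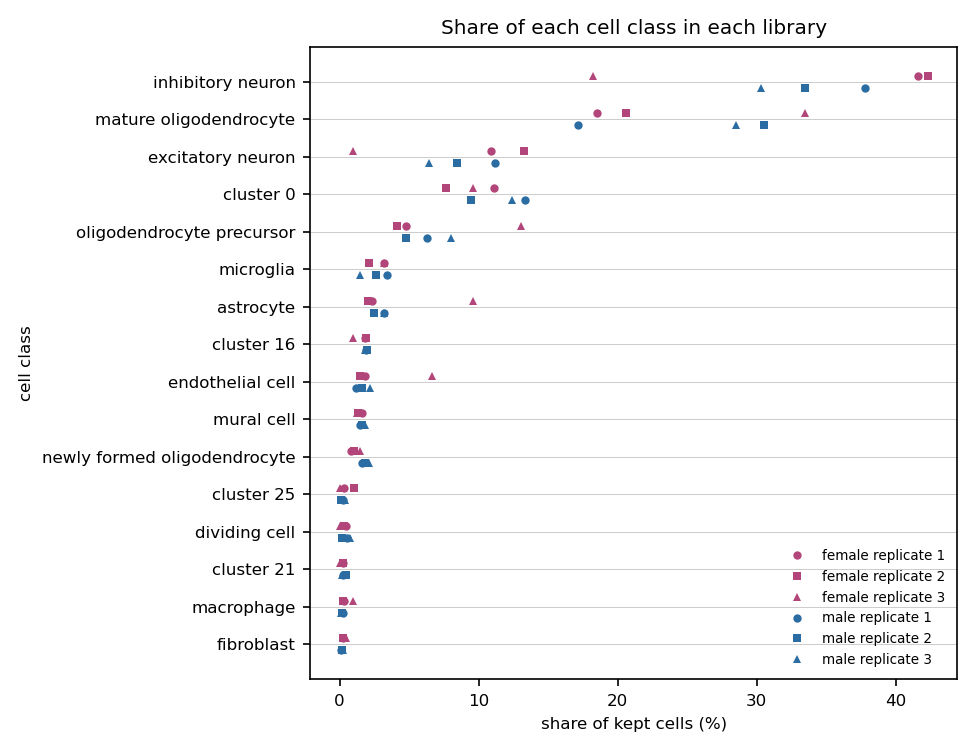
Share of kept cells (%, horizontal axis) in each of 16 cell classes (vertical axis), with 1 point per library coloured by sex and shaped by replicate number. Female replicate 3 has 18.2% inhibitory and 0.985% excitatory neurons. In newly formed oligodendrocytes the 3 female points lie below the 3 male points (1.10% and 1.85% on average).

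In all cells together, where the question was which genes differ by sex in the region as a whole, the genes that differed lay on the sex chromosomes. Xist (ENSMUSG00000086503, X:103460366-103483254, minus strand, mm10), the noncoding RNA that silences an X chromosome in female cells, stood at 843 ± 62.2 CPM (UMIs per 1000000 UMIs of the library) in female and 0.767 ± 0.904 in male libraries (SD, n = 3 each), 9.87 ± 0.74 apart on the log2 scale (female minus male, ± SE, adjusted p = 0.00411). Of the Y-linked genes, Ddx3y (ENSMUSG00000069045, Y:1260771-1286629), an RNA helicase, stood at 0.0296 and 108 ± 4.94 (-11.37 ± 0.29, adjusted p = 4.86e-06). Eif2s3y (ENSMUSG00000069049, Y:1010543-1028847), a translation initiation factor, was at 0.0415 and 87.6 ± 4.83 (-11.03 ± 0.57, adjusted p = 0.000433). Uty (ENSMUSG00000068457, Y:1096861-1245759) and Kdm5d (ENSMUSG00000056673, Y:897788-956786), which act on histone methylation, followed. Uty was at 24.7 ± 1.83 in male libraries (-9.64 ± 0.28, adjusted p = 6.84e-06). Kdm5d was at 26.2 ± 4.995, at least 1023-fold lower in female libraries, which held 0 UMIs of it (floor of 3 UMIs over the group, adjusted p = 0.00205). Tsix (ENSMUSG00000085715, X:103431517-103484957, plus strand) was 4.52 ± 0.44 higher in females (7.66 ± 4.88 against 0.405 ± 0.0756, adjusted p = 0.0244). Tsix covers all 22.89 kb of Xist on the other strand and the strand of counting is not given in the sources used here, so its reads are of uncertain origin. The last was Gm29650 (ENSMUSG00000099876, Y:1048393-1049134), a Y-linked noncoding RNA at 2.13 ± 0.421 in males and at least 70.9-fold lower in females (adjusted p = 0.0311). That made 7 of 16080 genes, 2 higher in females and 5 in males, with 369 genes under an unadjusted 0.05 and 6.71% of genes with no overlap between the sexes, where chance gives 10%. Without male replicate 3 the count was 4 and the Xist call ended (9.67). The Tsix call ended without male replicate 1, 2 or 3 (4.60, 4.32 and 4.59) and that of Gm29650 without any single library except female replicate 3 (-8.73 to -9.21) and with thinned cells (-7.31). The fitted size rests on few UMIs where a sex has next to none. Xist was 11.69 without male replicate 2, Tsix 3.93 without female replicate 1, Eif2s3y -14.56 without female replicate 1 and -9.47 without female replicate 2, and Ddx3y -10.71 without female replicate 2.

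**Figure D2:**
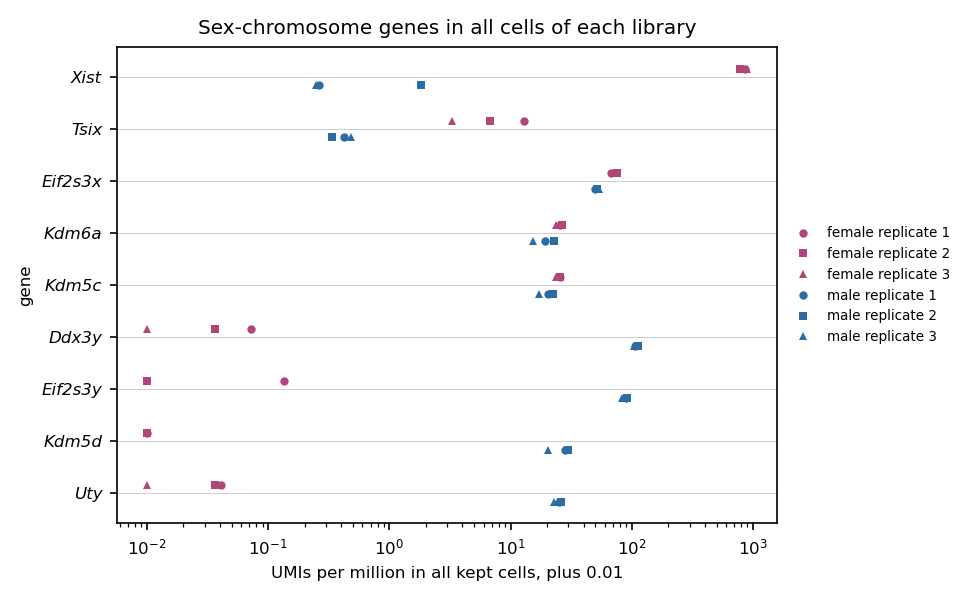
CPM over all kept cells plus 0.01 (horizontal axis, log scale) of 9 X-linked and Y-linked genes (vertical axis), with 1 point per library coloured by sex and shaped by replicate number. Xist averages 843 in female libraries, Ddx3y averages 108 in male libraries, and the X gene Eif2s3x lies between 51.8 and 72.5 in the group means.

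Among the fixed lists, X genes that escape inactivation leaned to females in all cells. Eif2s3x (ENSMUSG00000035150, X:94188707-94212862), the X partner of Eif2s3y, stood at 72.5 ± 3.86 and 51.8 ± 1.94 CPM (+0.48 ± 0.12 on the log2 scale). It was, with Xist and Tsix, 1 of 3 genes that passed when adjusted over the list alone, beside 2 of the list's 10 genes over all genes. The histone demethylases Kdm6a (25.3 ± 1.47 and 19.0 ± 3.70) and Kdm5c (25.02 ± 1.10 and 19.96 ± 2.58) and Pbdc1 (68.9 ± 1.64 and 58.1 ± 0.579) also had no overlap between the sexes but did not pass. Nor did Ddx3x (124 ± 30.8 and 98.2 ± 17.6). As a set, 9 of the 10 X genes were positive (camera, adjusted p = 3.04e-12) and all 4 Y genes negative (adjusted p = 1.1e-21), and both had adjusted p = 0.0733 with an estimated correlation. Cholesterol synthesis genes were lower in females in 19 of 22 members, with a median of -0.15 (camera, adjusted p = 0.000252, and 0.0733 with an estimated correlation). So were 14 of 16 glucocorticoid-responsive genes, with a median of -0.26 (adjusted p = 1.37e-06, and 0.599 with an estimated correlation), such as Fkbp5, a chaperone that the hormone induces, at 8.44 ± 1.21 and 13.01 ± 2.33. Neuropeptides were positive in 25 of 35 members (adjusted p = 0.00358, and 0.610 with an estimated correlation). Avp, the vasopressin gene, stood at 608, 979 and 523 in female and 246, 218 and 439 in male libraries (+1.23 ± 0.33) but did not pass. Monoamine, acetylcholine and nitric oxide genes (12 of 14 positive, adjusted p = 0.0217, and 0.219 with an estimated correlation), patterning factors (18 of 31, 0.0330, and 0.610 with an estimated correlation) and hemoglobin genes (5 of 5, 0.000808, and 0.579 with an estimated correlation) were called higher in females. Mitochondrially encoded genes were called lower (2 of 13 positive, 0.0356, and 0.610 with an estimated correlation). Hemoglobin followed single libraries more than sex: Hbb-bs stood at 127, 240 and 2.46 in female and 185, 7.61 and 6.66 in male libraries. Camera called none of the other 9 lists: steroid receptors and enzymes (adjusted p = 0.296), peptide receptors (0.315), genes reported as sexually dimorphic (0.521), early response genes (0.296), interferon response genes (0.171), MHC class I genes (0.762), clock genes (0.608), GABA-A and glycine receptor subunits (0.178) and glutamate receptor subunits (0.996). The calls of neuropeptides and monoamine genes ended without female replicate 2 or male replicate 2, and that of mitochondrial genes without female replicate 1 or 3 or male replicate 1 or 2. Patterning factors lost theirs without female replicate 2 or male replicate 3, and hemoglobin without male replicate 2.

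Within inhibitory neurons, where the question was which genes differ by sex inside a class, X and Y genes led again. Xist stood at 832 ± 72.1 CPM in female and 0.550 in male libraries (adjusted p = 2.28e-09). In male libraries Ddx3y was at 125 ± 4.80, Eif2s3y at 86.9 ± 6.13 and Uty at 29.6 ± 1.62, while Kdm5d was at least 579-fold and Gm29650 at least 45.7-fold lower in females. Adjusted over the list alone, 6 of 9 X genes were higher in females, among them Kdm6a (ENSMUSG00000037369, X:18162575-18279936; 25.3 ± 2.501 and 15.97 ± 0.701), Eif2s3x (90.4 ± 11.7 and 62.9 ± 3.59) and Kdm5c (30.8 ± 5.89 and 19.8 ± 1.38). Adjusted over the list alone, Esr1 (ENSMUSG00000019768, 10:4611593-5005614), the estrogen receptor alpha, was also higher in females (15.9 ± 3.47 and 10.3 ± 1.67; +0.71 ± 0.16). So were the peptide genes Nms (19.99 ± 4.90 and 11.1 ± 2.81) and Avp (ENSMUSG00000037727, 2:130580620-130582554; 1632 ± 362 and 762 ± 341), the calcitonin receptor Calcr, the immediate early genes Fos (646 ± 38.1 and 452 ± 90.1) and Fosb, and the clock-related receptor Rorb (130.4 ± 10.5 and 88.4 ± 9.52). Greb1 (ENSMUSG00000036523, 12:16670615-16800886), which estrogen induces in other tissues, was lower in females on the same footing (1.16 ± 1.06 and 4.13 ± 1.04; -1.30 ± 0.27). Likewise lower were the glucocorticoid-responsive Sgk1 (15.1 ± 2.39 and 24.7 ± 3.75) and Fkbp5 (ENSMUSG00000024222, 17:28399094-28517527; 9.43 ± 2.68 and 14.2 ± 1.85). As sets, early response genes (23 of 28 positive, camera adjusted p = 3.75e-07, and 0.333 with an estimated correlation) and neuropeptides (22 of 34, 3.00e-05, and 0.198 with an estimated correlation) were higher. Glucocorticoid-responsive genes were lower in females (9 of 11 negative, 0.000477, and 0.264 with an estimated correlation), though the list's median in female replicate 3 (0.13) lay above those in male replicates 2 and 3 (-0.01 and 0.11). Mitochondrially encoded genes were lower (11 of 13 negative, 0.00120, and 0.467 with an estimated correlation), a call that ended without female replicate 3. All told 7 of 14081 genes passed (931 under an unadjusted 0.05; 12.6% without overlap, chance 10%), 11 without female replicate 1 and 17 without male replicate 3.

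In mature oligodendrocytes, 13 of 13 glucocorticoid-responsive genes were lower in females, with a median of -0.69 (camera, adjusted p = 2.44e-11, and 0.210 with an estimated correlation). The libraries overlapped, since the list's median in female replicate 3 (0.43) lay above those in male replicates 1 and 2 (0.39 and -0.21). Adjusted over the list alone, 3 of them passed: Tsc22d3, which restrains inflammation (99.4 ± 18.6 and 149 ± 33.1), Ddit4, an inhibitor of mTOR signalling (161 ± 55.6 and 252 ± 43.4), and Cdkn1a, a brake on the cell cycle (16.9 ± 6.20 and 35.1 ± 3.03). Per gene, 6 of 11011 passed (349 under an unadjusted 0.05; 8.50% without overlap, chance 10%): Xist (549.8 ± 76.2 and 0.689), the 4 Y genes with Ddx3y at least 478-fold lower in females, and Tma16. The last (ENSMUSG00000025591, 8:66473118-66486530), a ribosome assembly factor, was at 53.9 ± 9.23 and 120.5 ± 9.97 (-1.23 ± 0.15, adjusted p = 0.0202). The Tma16 call ended without any single library except female replicate 3 (-1.16 to -1.31) and with thinned cells (-1.10). Tac1 (ENSMUSG00000061762, 6:7554879-7565834), which encodes substance P, was lower in females adjusted over the list alone (31.8 ± 14.5 and 81.5 ± 7.87; -1.14 ± 0.22). That was against the direction of its list, in which 22 of 24 neuropeptides were positive (3.61e-07, and 0.467 with an estimated correlation; ended without female replicate 2). Early response genes (21 of 28, 0.00108; ended without female replicate 1 or male replicate 1 or 2) and GABA-A and glycine receptor subunits (12 of 13, 0.000611; ended without female replicate 2) were higher and cholesterol synthesis genes lower (19 of 22 negative, 0.000611; ended without female replicate 2 or male replicate 1), all 3 with adjusted p = 0.478 with an estimated correlation. UMIs of neuronal genes in these cells have to be read against the free RNA given above.

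In oligodendrocyte precursors, cholesterol synthesis genes were lower in female libraries in 21 of 22 members, with a median of -0.30 (camera, adjusted p = 4.24e-12, and 0.172 with an estimated correlation). Acat2 (93.7 ± 22.0 and 139 ± 28.7) and Fdft1, the enzyme that makes squalene (101 ± 14.3 and 147 ± 18.4), are examples, though no member passed on its own. Glucocorticoid-responsive genes were lower (8 of 10 negative, 0.00195, and 0.327 with an estimated correlation; ended without female replicate 1 or male replicate 2). Neuropeptides were higher (12 of 14 positive, 8.14e-11, and 0.247 with an estimated correlation; ended without female replicate 2). Avp was at 56.0, 114 and 0 in female and 26.5, 22.5 and 33.4 in male libraries, and 0.81 without female replicate 2 in place of 1.64 on the log2 scale. Xist stood at 1660.3 ± 141 and 3.07. It and the 4 Y genes made the 5 of 9563 genes that passed (234 under an unadjusted 0.05; 7.73% without overlap, chance 10%; 10 without female replicate 3). Eif2s3x was higher in females adjusted over the list alone (68.2 ± 1.30 and 35.3 ± 5.97; +0.87 ± 0.20). The X and Y lists passed here also with an estimated correlation (adjusted p = 0.0285 for each).

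In cluster 0, astrocytes and endothelial cells, all genes called but Lrrc58 were X or Y genes. In cluster 0, 7 of 11601 genes passed (554 under an unadjusted 0.05; 19 without male replicate 1): Xist (1390.0 ± 89.4 and 1.16), Tsix, the 4 Y genes and Lrrc58. Lrrc58 (ENSMUSG00000034158, 16:37868389-37888858) was lower in females at 104 ± 20.9 and 171 ± 27.2 (-0.83 ± 0.15, adjusted p = 0.0363). The Lrrc58 call ended without female replicate 1 (-0.89), 2 (-0.70) or 3 (-0.85) or male replicate 2 (-0.79). It also ended with DESeq2 (-0.80), thinned cells (-0.80) or a minimum count of 50 (-0.82), and that of Tsix with DESeq2 (3.31 in place of 3.64). In astrocytes, Xist was at least 788-fold higher in females (1731 ± 228), and Ddx3y at least 45.0-fold and Eif2s3y at least 54.7-fold lower. That made 3 of 6877 genes (48 under an unadjusted 0.05), and 1 without male replicate 1 or 2. In endothelial cells, Xist (790.0 ± 142 and 1.49) and Ddx3y (at least 39.9-fold lower in females) were the 2 of 5310 that passed (64 under an unadjusted 0.05), and 1 did without female replicate 1 or 2 or male replicate 2. Angptl4, a lipase inhibitor that glucocorticoids induce, was lower in female endothelial cells adjusted over the list alone (23.8 ± 21.6 and 105 ± 75.0). There, 11 of 11 glucocorticoid-responsive genes were negative (camera, adjusted p = 3.76e-06, and 0.535 with an estimated correlation; ended without female replicate 2). The list's median in female replicate 3 (0.42) nonetheless lay above those in male replicates 1 and 2 (-0.14 and 0.04). Neuropeptides (8 of 11 positive, 0.00225), interferon response genes (11 of 14, 0.0167), GABA-A and glycine receptor subunits (3 of 3, 0.0437) and hemoglobin genes (5 of 5, 0.00859) were called higher in endothelial cells, and mitochondrial genes lower (0 of 12 positive, 0.00148). With an estimated correlation each of these had adjusted p = 0.535 or larger, and each call ended without at least 2 of the libraries in turn. Early response genes were higher in female astrocytes (13 of 14 positive, 0.000421; ended without female replicate 2) and mitochondrial genes lower (1 of 12 positive, 0.0324; ended without female replicate 3 or male replicate 2), both with 0.944 with an estimated correlation.

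Excitatory neurons, cluster 16, microglia, mural cells and newly formed oligodendrocytes held fewer than 20 cells in female replicate 3. They were compared, as a choice made after seeing the data, in the other 5 libraries (2 female, 3 male). Female excitatory neurons had more Cartpt (ENSMUSG00000021647, 13:99898489-99901091), the CART peptide gene, at 307 ± 95.3 and 130.4 ± 23.2 (+1.27 ± 0.19, adjusted p = 0.0338; ended without female replicate 2, 0.91, or male replicate 1, 1.28, or 2, 1.14, at a minimum count of 50, 1.27, and at resolution 2.0, 1.41). In cluster 16 Cartpt was lower in females (128 ± 20.8 and 377 ± 74.9; -1.50 ± 0.18, adjusted p = 4.03e-05). There Npy (ENSMUSG00000029819, 6:49822710-49829507), neuropeptide Y, was higher (703 ± 6.66 and 289 ± 120; +1.20 ± 0.19, adjusted p = 0.00311). The Cartpt call in cluster 16 ended with thinned cells (-1.02) and that of Npy at a minimum count of 50 (1.18). DESeq2 called none of Npy, Vip and Myh7 in cluster 16, of Flt1, Itm2a, Crh and Avp in microglia, of Avp and Pcdhb9 in newly formed oligodendrocytes, or of Xist, Tsix and Gm29650 in excitatory neurons. Whether Cartpt differs between these classes in its sex difference was not tested. Vip in cluster 16 followed 1 library, with 2.49 and 10.9 in female and 35.5, 291 and 18.5 in male libraries. Its call (-4.13 ± 0.74) ended without male replicate 2 (-1.99), as did that of Myh7 (1.68 in place of 1.82). Excitatory neurons also had more Npy2r (24.7 ± 0.888 and 15.04 ± 0.620) and Th, the rate-limiting enzyme of dopamine synthesis (9.36 ± 0.255 and 2.57 ± 1.24), in females adjusted over the list alone. Avp was at 44.0 and 1122 in female and 22.3, 26.7 and 29.6 in male libraries (4.54 on the log2 scale, 0.81 without female replicate 2). In microglia, the endothelial markers Flt1 (13.5 and 18.8 against 0 in all 3 male libraries, at least 12.7-fold higher) and Itm2a (24.3 and 83.7 against 11.7, 3.39 and 9.69) and the peptides Crh and Avp were called higher in females. These calls ended without male replicate 2, for Itm2a and Avp also without female replicate 2, and for Crh also without female replicate 1 or male replicate 3. With doublets kept, those of Itm2a (2.46), Crh (1.16) and Avp (2.25) ended, and that of Avp also with thinned cells (1.43) or a minimum count of 50 (2.14). In newly formed oligodendrocytes Avp (67.6 ± 29.0 and 14.3 ± 7.90; ended without female replicate 2 or male replicate 2, 1.75 and 1.87 in place of 2.48) and the protocadherin Pcdhb9 (92.1 ± 16.2 and 29.8 ± 3.79; ended without female replicate 2 or male replicate 2, 1.77 and 1.45 in place of 1.58) were higher. So was Gm42418, which overlaps a ribosomal RNA repeat, at 1.40. Its call ended without female replicate 2 (0.46) or male replicate 2 or 3 (1.45 and 1.11), with total-count scaling (1.37), DESeq2 (1.41), doublets kept (1.35) or stricter cells (1.42), and at a minimum count of 50 (1.39). The pseudogene Rps18-ps3 was lower (-1.31). Its call ended without the same 3 libraries (-1.22, -1.27 and -1.11), with DESeq2 (-1.33), doublets kept (-1.38) or thinned cells (-1.30), and at a minimum count of 50 (-1.30). The source of the reads of both is uncertain. At that minimum count the Pcdhb9 call ended too (1.59). Glucocorticoid-responsive genes were negative in 10 of 10 members in microglia (camera, adjusted p = 9.83e-06, and 0.206 with an estimated correlation) and 8 of 8 in mural cells (0.00159, and 0.389 with an estimated correlation). Early response genes were lower in females in microglia (22 of 26 negative, 1.23e-05, and 0.387 with an estimated correlation) and mural cells (21 of 26, 6.46e-05, and 0.389 with an estimated correlation; ended without female replicate 1). They were higher in excitatory neurons (21 of 27 positive, 3.22e-06, and 0.374 with an estimated correlation; ended without female replicate 2). The counts were 8 of 12626 genes in excitatory neurons (735 under an unadjusted 0.05; 21.1% without overlap, chance 20%; 5 without female replicate 2, 16 without male replicate 3) and 9 of 9229 in cluster 16 (17 without female replicate 1, 27 without male replicate 1). They were 7 of 7425 in microglia (12, 20, 64 and 3 without female replicates 1 and 2 and male replicates 1 and 2), 3 of 5535 in mural cells (27 and 8 without female replicates 1 and 2) and 7 of 7867 in newly formed oligodendrocytes (25, 13 and 3 without female replicate 1 and male replicates 1 and 2).

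**Figure D3:**
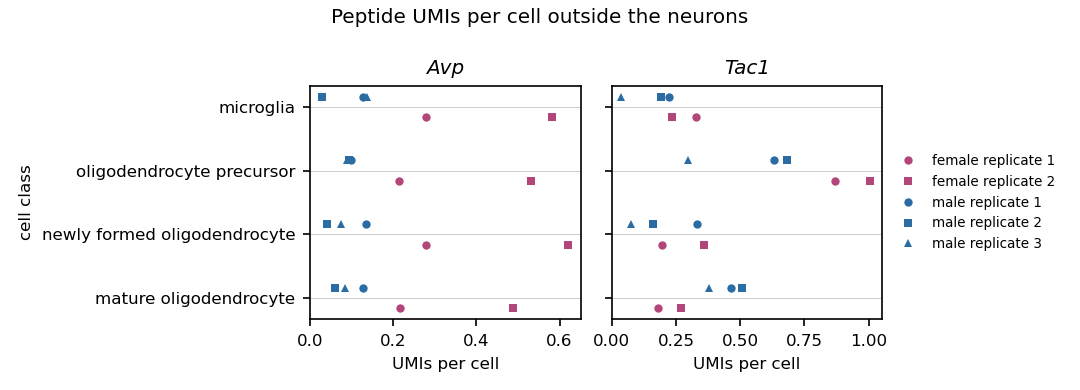
UMIs per cell (horizontal axis) of Avp and of Tac1 in 4 classes that are not neurons (vertical axis), with 1 point per library coloured by sex and shaped by replicate number, for the 5 libraries other than female replicate 3. Avp lies highest in female replicate 2 in each class, from 0.489 to 0.621 UMIs per cell.

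Over the 12 comparisons of the sexes, glucocorticoid-responsive genes were called lower in females in 9 and higher in 0, and neuropeptides higher in 9 and lower in 0. Early response genes went both ways, higher in 6 and lower in 2. With an estimated correlation none of these 3 lists was called in any of the 12. The 12 comparisons draw on the same libraries, and all cells include the cells of each class, so they are not independent.

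The next question was whether the sex difference differs between inhibitory and excitatory neurons. For Ucn3 (ENSMUSG00000044988, 13:3940688-3945349), urocortin 3, a peptide of the stress system, a difference was called in each alternative that gave a value for it. The log2 ratio of inhibitory to excitatory neurons was -2.36 and -2.67 in female replicates 1 and 2 and -5.74, -5.53 and -5.71 in the male replicates, so the excess in excitatory neurons was smaller in females (+3.54 ± 0.31, adjusted p = 5.56e-26, and 1.71 with stricter cells). Female replicate 3 held no UMI of it in either class, a ratio of 0.00. Ucn3 was low in inhibitory neurons, at 2.25 ± 3.997 CPM against 25.7 ± 23.4 in excitatory neurons (SD, n = 6). The ratios therefore rest on low values in inhibitory neurons. The source of its UMIs there, free RNA included, was not tested. For Cartpt the ratios overlapped, at -0.61 and -1.19 in these female and 0.08, 0.29 and -0.96 in the male libraries (-1.02 ± 0.08, adjusted p = 1.01e-34), and the call ended with DESeq2 (-0.33). Avp was at 4.84 and 0.55 against 4.68, 4.37 and 5.28 (-2.56 ± 0.15, adjusted p = 9.77e-61), but that value was -3.95 without female replicate 1, turned to 0.22 without female replicate 2 and lost its call without female replicate 3 (-2.65). Npy (-1.00) lost its call without female replicate 2 (-0.34), Rgs16 (+0.88) without female replicate 2 (0.63) or male replicate 2 (0.77), and Th (-1.34) without male replicate 1 (-1.41). Gal (+0.52), the galanin gene, lost it without female replicate 1 (0.21) or 3 (0.52) and turned to -0.10 without male replicate 1. In all, 34 of 12401 genes passed, 17 in each direction (612 under an unadjusted 0.05), but 1, Ucn3, by DESeq2, and 14, 17 and 20 without female replicates 2 and 3 and male replicate 2. As sets, hemoglobin genes (3 of 3 positive, adjusted p = 4.09e-08, and 0.164 with an estimated correlation; ended without female replicate 2), clock genes (13 of 18 positive, 6.80e-05, and 0.161 with an estimated correlation) and Y genes (median -0.45, 4.09e-08, and 0.164 with an estimated correlation; ended without any male library) were called.

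Neuronal subtypes were counted to ask whether any is more frequent in 1 sex. The 18268 neurons, clustered on their own, made 28 clusters. Cluster 16 of this set (1500 cells, led by Vamp1, Lrrc4b and Plcxd2) made up 6.75 ± 0.845% of neurons in female and 9.51 ± 1.86% in male libraries (-0.53 ± 0.22 on the log2 scale). Cluster 2 (1045 cells), whose leading genes Avp, Vip and Nms mark neurons of the suprachiasmatic clock, made up 7.90 ± 1.79% and 4.96 ± 1.32% (+0.61 ± 0.29). Cluster 22 (510 cells, led by Rrad, Fosb and Grp) was +0.93 ± 0.46. None passed. edgeR called 0 of 28 clusters, with 1 under an unadjusted 0.05 and adjusted p = 0.618 at the smallest, and exact permutation of the shares called 0, with 0 under an unadjusted 0.05.

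Inhibitory and excitatory neurons were compared within each library to ask which receptor, peptide and patterning genes part the main transmitter classes. The LIM homeobox genes Lhx6 (ENSMUSG00000026890, 2:36081953-36105408), at 26.8 ± 3.34 CPM in inhibitory and 0.824 ± 0.907 in excitatory neurons (SD, n = 6; +4.28 ± 0.16 on the log2 scale), and Lhx8 (58.2 ± 11.7 and 2.81 ± 1.70; +3.88 ± 0.11) were higher in inhibitory neurons. Otp (ENSMUSG00000021685, 13:94875602-94885130), which specifies neuroendocrine neurons (2.59 ± 1.62 and 141 ± 39.0; -5.19 ± 0.08), and Lhx2 (-3.11 ± 0.13) were higher in excitatory ones. Among the peptides, Npy (208 ± 95.3 and 19.3 ± 13.5; +3.19 ± 0.08), Nts, the neurotensin gene (+1.81 ± 0.05), and Gal (297 ± 115 and 87.9 ± 63.2; +1.67 ± 0.08) were higher in inhibitory neurons. Trh (ENSMUSG00000005892, 6:92242061-92244650), thyrotropin-releasing hormone (33.1 ± 19.1 and 1136 ± 892; -4.83 ± 0.09), Adcyap1, PACAP (3.84 ± 2.23 and 83.5 ± 15.6; -4.36 ± 0.08), Nxph4 (-5.46 ± 0.12) and Ucn3 (-3.31 ± 0.17, and -4.63 without female replicate 2) were higher in excitatory neurons. Avp was 3.15 ± 0.24 higher in inhibitory neurons and 4.73 without female replicate 2, and its call ended with no library block (2.23). Each gene named here had adjusted p = 0.00765 or smaller (edgeR) and the same direction in 6 of 6 libraries, except Lhx2 and Ucn3. These 2 had a ratio of 0 in female replicate 3. That library held 4 excitatory neurons, so its directions weigh little.

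By list, early response genes were mostly higher in inhibitory neurons, 21 against 1 of 27 tested (camera, adjusted p = 5.70e-12, and 0.120 with an estimated correlation), such as Nr4a2 (17.8 ± 2.39 and 1.69 ± 1.02), Egr4 (71.3 ± 16.8 and 19.4 ± 10.98) and Arc, a synaptic plasticity gene (46.2 ± 17.6 and 22.0 ± 7.65). Clock genes followed, 12 against 1 of 18 (9.86e-07, and 0.120 with an estimated correlation), with Rorb at 114 ± 26.6 and 34.0 ± 17.5 and Per2 at 18.4 ± 4.50 and 8.21 ± 4.65. Next came glutamate receptor subunits, 7 against 0 of 16 (0.00106, and 0.120 with an estimated correlation), with the kainate receptor subunits Grik3 (25.5 ± 4.88 and 4.07 ± 2.10) and Grik1 (15.7 ± 3.36 and 8.18 ± 4.56). Neuropeptides (18 higher and 12 lower of 32, 0.0293, and 0.131 with an estimated correlation; ended without female replicate 3 or male replicate 2) and patterning factors (14 and 10 of 28, 0.0404, and 0.379 with an estimated correlation; ended without female replicate 2 or 3 or male replicate 3) went both ways. Hemoglobin genes (3 and 0 of 3, 0.0293, and 0.379 with an estimated correlation; ended without female replicate 2) and mitochondrial genes (2 and 0 of 13, 0.0441, and 0.509 with an estimated correlation; ended without female replicate 1 or male replicate 1 or 3) were called higher, with mt-Co1 at +0.28 ± 0.06 (ended with no library block, 0.30, and with classes set by transmitter UMIs, 0.16). Peptide receptors were not called (10 and 14 of 35, 0.0539) but held large single differences, Vipr2, the VIP receptor of clock neurons (11.8 ± 7.87 and 1.01 ± 0.836), upward and Trhr (10.1 ± 3.57 and 22.1 ± 8.12) downward. GABA-A and glycine receptor subunits split 5 and 6 of 18, with Gabrg1 at +0.23 ± 0.04, a call that ended in 4 alternatives (0.05 at resolution 2.0). Monoamine genes split 3 and 3 of 10, with Th (16.9 ± 7.34 and 4.57 ± 4.21), the vesicular transporter Slc18a2 (+1.60 ± 0.13) and the nitric oxide synthase Nos1 (-0.84 ± 0.06). Of genes reported as sexually dimorphic, Ecel1 was +2.17 ± 0.08 and Calb1, calbindin, -0.51 ± 0.04. Esr1 was higher in inhibitory neurons (13.7 ± 4.12 and 8.19 ± 5.68; +0.40 ± 0.10, adjusted p = 0.00154), a call that ended in 4 alternatives, among them classes set by transmitter UMIs (0.04). Mt1, of the glucocorticoid list, was higher in inhibitory ones (+0.70 ± 0.05). In all 2254 of 11411 genes kept out of the clustering passed, 1078 higher in inhibitory and 1176 in excitatory neurons.

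**Figure D4:**
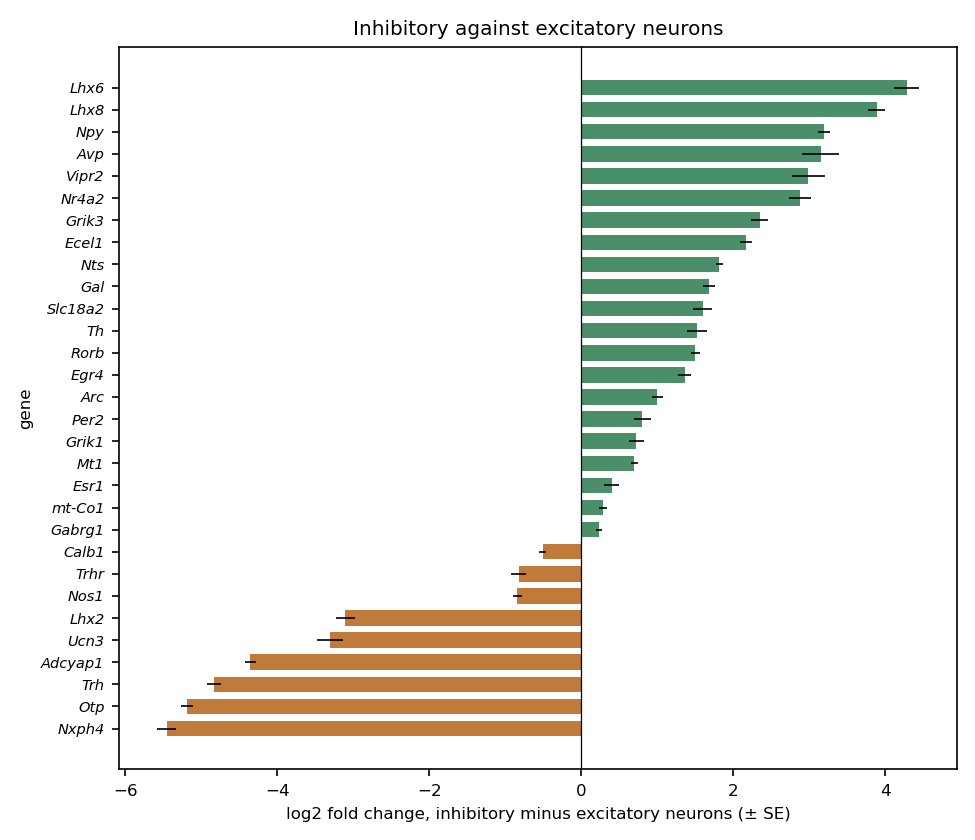
Log2 fold change of inhibitory minus excitatory neurons (horizontal axis, bars with SE from the edgeR fit over 6 libraries) of 30 listed genes (vertical axis), green where higher in inhibitory and brown where higher in excitatory neurons. The bars run from -5.46 for Nxph4 and -5.19 for Otp to 4.28 for Lhx6.

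Hormone receptor, peptide and monoamine genes were then located among the cell classes. The 6 classes with at least 20 cells in each of 6 libraries leave out excitatory neurons and cluster 16. Among these 6, Prlr, the prolactin receptor, was highest in inhibitory neurons (79.7 ± 30.9 CPM against 22.1 ± 27.7 in astrocytes, the next class, SD, n = 6). So was Gal (283 ± 106 and 44.6 ± 53.7), each higher in 6 of 6 libraries. The mean of the paired log2 differences of Gal (pseudocount 1) was 4.18, and 3.41 without male replicate 3. In the edgeR fit the difference was smaller, 2.28 ± 0.25. Esr1 (13.1 ± 3.70, and 5.13 ± 6.68 in cluster 0), Pgr, the progesterone receptor (28.0 ± 10.6 and 21.7 ± 8.78), and Th (16.2 ± 6.94 and 6.76 ± 1.97) were also highest in inhibitory neurons but in 5, 4 and 5 libraries. Cyp19a1, aromatase, was near the floor (0.716 ± 0.399 in cluster 0 and 0.551 ± 0.354 in inhibitory neurons). Exact two-sided sign flips called 0 of 114 genes: 45 reached the smallest p that 6 libraries allow, 0.03125, which adjusted to 0.0792. edgeR with the library as block, a test added after that result was seen, called 47 of 59 genes.

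Across 11 classes in 5 libraries, without female replicate 3, mural cells held the most Gper1 (ENSMUSG00000053647, 5:139423151-139427800), a membrane estrogen receptor, at 372 ± 115 against 18.9 ± 11.2 in endothelial cells (SD, n = 5; edgeR, +4.64 ± 0.27, adjusted p = 1.50e-22). They also held the most of the neuropeptide Y receptor Npy1r (118 ± 23.02; +2.89 ± 0.16). Astrocytes held the most Hsd11b1, which regenerates active glucocorticoid (55.4 ± 19.3 against 2.83 ± 3.73 in endothelial cells; +4.52 ± 0.57), Maob (35.8 ± 3.71; +1.30 ± 0.32) and the growth hormone receptor Ghr (65.5 ± 27.3; +1.02 ± 0.19). Mature oligodendrocytes held the most Srd5a1, which makes dihydrotestosterone (71.5 ± 12.8 against 21.4 ± 4.37 in newly formed ones; +2.28 ± 0.18). Oligodendrocyte precursors held the most Sstr1 (50.7 ± 7.26; +2.46 ± 0.28). Endothelial cells were highest for Igf1r (352 ± 50.1; +2.72 ± 0.18), Maoa (215 ± 43.4; +1.79 ± 0.14) and Tspo (219.9 ± 56.7; +0.85 ± 0.18). Microglia were highest for Gch1 (225 ± 48.7; +1.55 ± 0.15). Cluster 0 was highest for the opioid genes Penk (3028 ± 229 against 345 ± 57.1 in inhibitory neurons; +3.19 ± 0.27) and Pdyn (178 ± 20.3; +3.00 ± 0.18) and for Tac1 (1753 ± 361; +3.23 ± 0.32) and Mchr1 (59.2 ± 10.8; +2.32 ± 0.20). Cluster 16 had the most Esr1 (22.2 ± 8.68 against 13.1 ± 4.14 in inhibitory neurons; +0.74 ± 0.18, adjusted p = 0.000248), Th (79.4 ± 60.6; +1.73 ± 0.19) and Tacr3 (23.3 ± 5.62; +1.79 ± 0.20). Excitatory neurons held the most Adcyap1 (82.7 ± 15.3; +3.70 ± 0.49, and 6.44 without female replicate 1), Nxph4 (42.5 ± 6.997; +2.42 ± 0.31, 3.06 without female replicate 2 and 4.48 with doublets kept) and Nos1 (56.1 ± 10.96; +0.82 ± 0.12). Prlr did not part the top pair of classes (97.3 ± 15.6 in excitatory neurons and 94.4 ± 26.4 in cluster 16, edgeR, adjusted p = 0.760). Nor did Pgr (34.5 ± 7.53 in excitatory and 31.7 ± 6.20 in inhibitory neurons, adjusted p = 0.283). Gal did not pass either (319 ± 65.8 in inhibitory neurons and 128 ± 230.1 in mural cells; +0.75 ± 0.35, adjusted p = 0.0540), but was 3.45 and passed without female replicate 2. It also passed with doublets kept (1.24), stricter cells (0.98) and at resolution 2.0 (0.95). Without female replicate 1 or male replicate 2 it fell to 0.44 and 0.48. Each gene said to be highest was higher in 5 of 5 libraries. The pair of classes was picked on the same counts that were tested. In all 45 of 66 genes passed: 6 of 10 steroid, 15 of 18 peptide receptor, 18 of 28 neuropeptide and 6 of 10 monoamine genes.

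**Figure D5:**
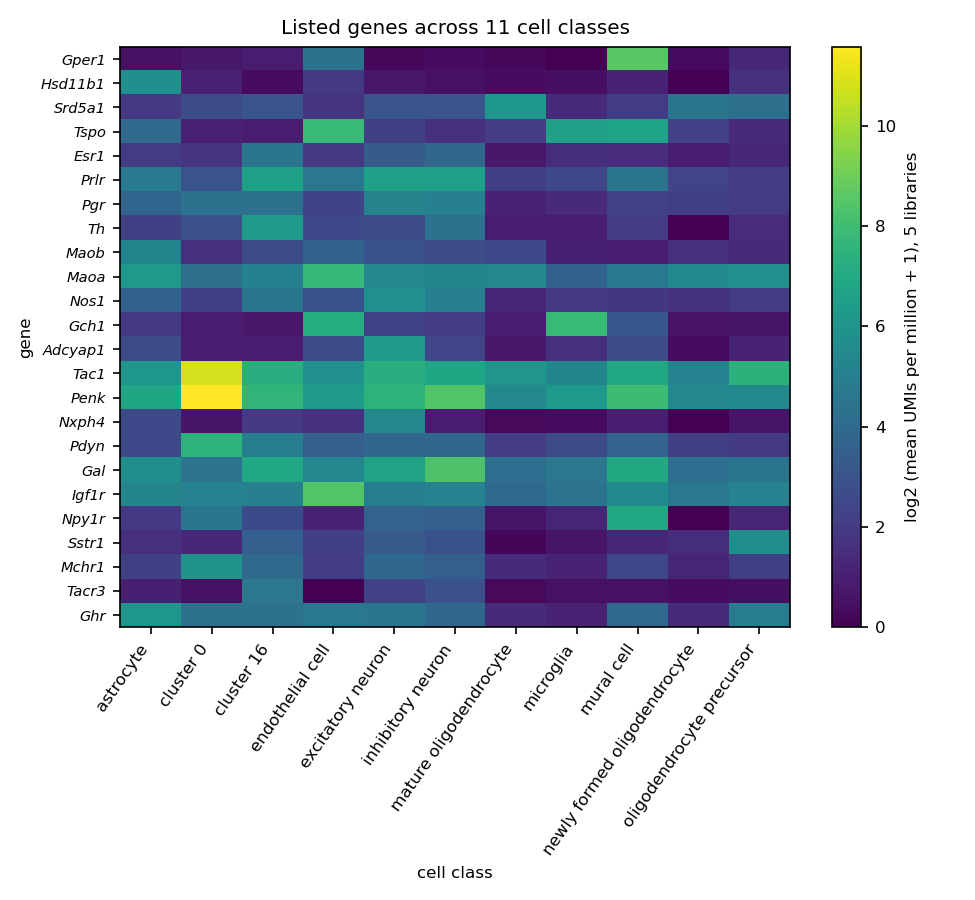
Mean CPM plus 1 (log2, colour) of 24 listed genes (vertical axis) in 11 cell classes (horizontal axis), over the 5 libraries other than female replicate 3. Gper1 peaks in mural cells at 372, Hsd11b1 in astrocytes at 55.4 and Penk in cluster 0 at 3028.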

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

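The tests of peptide UMIs outside the neurons, of inhibitory neurons without the cluster led by Avp and of the thinned and left-out glucocorticoid medians were chosen only after the results they bear on were seen, as was the comparison across 11 classes in 5 libraries.

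Neuropeptide genes were called higher in female libraries in classes that are not neurons, as in oligodendrocyte precursors, where 12 of 14 were positive. With an estimated correlation the list was called in 0 comparisons of the sexes. Without female replicate 2 the call ended in oligodendrocyte precursors and in mature and newly formed oligodendrocytes. It also ended in endothelial cells, and it held without each library in microglia and mural cells. Over 14 peptide genes in 4 such classes and 5 libraries, a median of 0.554 of the variance in UMIs per cell lay between libraries and 0.0723 between classes, with 11 genes varying more between libraries, which is consistent with free RNA from neurons that differs in amount between pools. For neurons caught in the same droplet, a median of 0.0696 of the peptide UMIs came from cells with at least 5 UMIs of the gene. That lies below the limit set, while Pcsk1n (0.731) lies above and Tac1 (0.285) and Sst (0.210) between the limits. This cannot decide on joined neurons, since called doublets had been left out before. A whole neuron may also hold under 5 UMIs of some of these genes. Vgf, for example, stood at 269 CPM in inhibitory neurons, whose median depth was 6899 UMIs. The limits for both peptide measures were also written afterwards, so they weigh less than a prediction made in advance. In Tac1, Chga and Pcsk1n more of the variance lay between classes (median 0.587, and 0.262 between libraries), and the source of these 3 is left open. Sex itself, joined neurons and any difference in dissociation between pools stay open.

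In inhibitory neurons Avp and Nms were higher in female libraries when adjusted over their list alone, and of the 10 genes that lead their cluster 7 were positive and 3 negative, none called over all genes. The cluster made up 11.5, 10.2 and 16.2% of inhibitory neurons in female and 8.61, 5.74 and 10.5% in male libraries. If a larger share of these neurons were the source, the female excess should fall when they are left out. Without the cluster the median log2 change of the 10 genes went from 0.22 to 0.28, a ratio of 1.27, but the members moved both ways by more than the median, so a larger share of these neurons cannot be told apart from a change within cells. Avp itself was +2.01 ± 0.54 without the cluster, where free RNA may be what remains.

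Glucocorticoid-responsive genes were lower in female libraries in most classes. Camera with the preset correlation called the list in 9 of 12 comparisons of the sexes, and in 0 with an estimated correlation. With each cell thinned to 1500 UMIs the median over 9 classes was -0.27 in place of -0.29, a ratio of 0.916. It kept its size, as predicted if depth per cell is not the cause. Thinning cannot decide on depth, though. Sums are scaled to their total, and thinning leaves the expected proportions within a cell as they were. It also left out 117 cells of female replicate 3 and 131 of male replicate 3. Single classes differed: thinned, excitatory neurons stood at 0.04 in place of -0.21. Newly formed oligodendrocytes stood at -0.11 in place of -0.30, with 4 genes tested in place of 9. The size also fell in microglia and mural cells and grew in the rest of the 9. For the median over classes a single library is argued against as the cause. Over 6 classes that median was -0.22. Leaving out each library in turn gave at the least -0.15, a ratio of 0.688, without male replicate 3. At the most it gave -0.38, without female replicate 3. Within classes, astrocytes turned to 0.22 in place of -0.17 without female replicate 2. Endothelial cells fell to -0.07 in place of -0.48 without male replicate 3. All of the 6 classes but astrocytes stayed negative without each library. The list's medians per library overlapped between the sexes in all 6 classes, and in mature oligodendrocytes they were -0.36, -0.55 and 0.43 in female and 0.39, -0.21 and 0.58 in male replicates 1, 2 and 3. A lower glucocorticoid response of female mice may fit these values, and so may a difference in handling or hour between the pools, which the labels do not give, so both stay open and untested.

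Female replicate 3 lay far from the other 5 libraries in the log2 ratio of inhibitory to excitatory neurons for 22 of the 30 genes named, where chance would put about 1 in 20 past the limit; it held 4 excitatory neurons. Its ratios were 8.53 for Lhx8, -9.95 for Otp, 0.00 for Lhx2, 13.25 for Avp, 7.94 for Nts, 8.94 for Gal, -8.37 for Nxph4 and for Adcyap1, 6.28 for Nr4a2 and 8.26 for Egr4. They were 9.40 for Rorb, 6.95 for Per2, Grik3 and Vipr2, 5.55 for Grik1, 1.65 for Gabrg1 and -3.35 for Trhr. They were 5.96 for Slc18a2 and Esr1, 8.58 for Ecel1, 1.92 for Mt1 and 1.20 for mt-Co1. Where a class held no UMI of a gene, the size of the ratio depends on the prior count of 2. In the comparison over 6 classes the log2 difference of female replicate 3 was -0.51 for Esr1 and -1.29 for Th, 2 of 5 genes tested. Over 11 classes, 3 of 24 genes had a library far from the rest: Adcyap1 in female replicate 1 (1.37), Penk in male replicate 3 (2.87) and Igf1r in female replicate 2 (2.19).

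By the edgeR test of the interaction, the sex difference in inhibitory minus that in excitatory neurons was 3.54 for Ucn3, 0.88 for Rgs16, 0.79 for Plcd4, -2.56 for Avp, -1.02 for Cartpt, -1.00 for Npy, -1.34 for Th and 0.52 for Gal in log2. DESeq2 kept the call of Ucn3 alone, whose value was 1.71 with stricter cells. Avp turned to 0.22 without female replicate 2 and Gal to -0.10 without male replicate 1. Npy and Rgs16 lost their calls without female replicate 2 and Th without male replicate 1. The Plcd4 call ended without female replicate 1, 2 or 3 (0.72, 0.95 and 0.79) or male replicate 2 or 3 (0.59 and 0.80), with doublets kept (0.66) and with stricter cells (0.69), and with thinned cells those of Plcd4 (0.56), Npy (-0.25), Rgs16 (1.49) and Gal (0.61) ended.

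The 6 libraries can be split into 3 and 3 in 10 ways, the sexes among them, too few for a share under 0.05. In all cells the sexes gave 7 genes and the highest other split 528, and 2 of 10 splits, the sexes included, gave at least 7. The highest split set female replicates 1 and 2 and male replicate 1 against the rest and points to a structure of the libraries that is not sex, as does a split of astrocytes with 985 genes (sexes 3; 2 of 10 with at least that many). The real and highest other counts were 7 and 23 in cluster 0, 2 and 7 in endothelial cells, 7 and 15 in inhibitory neurons, 6 and 15 in mature oligodendrocytes and 5 and 23 in oligodendrocyte precursors, each with 2 of 10 splits, the sexes included, at or above the real count. For the interaction they were 34 and 31 (1 of 10, the sexes alone), for neuronal cluster sizes 0 and 1 (10 of 10) and for called lists over the 6-library comparisons of sex 47 and 53 (2 of 10). Swapping the neuron classes within libraries gave 32 arrangements with the real one. The real arrangement alone reached its count of genes, 2254 against 2174 in the highest other (1 of 32). The classes were made by clustering these same cells, so a high count was built in and the swaps cannot decide on chance. Chance cannot be excluded for the 7 called lists, which another arrangement also reached (2 of 32).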

How the results depend on the processing

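A gene named in several comparisons was counted once in each. Of these results 106 were called, and 70 of them stayed called in all alternatives that gave a value. An alternative in which a gene was no longer tested was not counted. Over all alternatives the called results kept direction and call in 1293 of 1426 values, lost the call in 131 and turned in 2. Both turns were for the interaction. Avp was 0.22 without female replicate 2 (lowest -3.95 without female replicate 1). Gal was -0.10 without male replicate 1 (highest 1.10 without female replicate 2). Results not called, the 3 neuronal clusters included, stayed so in 616 of 671 values and passed in 54. The comparisons without female replicate 3, the edgeR tests across classes and the swaps were chosen after seeing the data.

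Without a filter on low counts, 6 genes were called by sex in astrocytes (3 with it), 62 in cluster 0 (7), 19 in endothelial cells (2), 40 in inhibitory neurons (7), 22 in mature oligodendrocytes (6), 18 in oligodendrocyte precursors (5), 38 in cluster 16 (9), 68 in excitatory neurons (8), 37 in microglia (7), 58 in mural cells (3) and 16 in newly formed oligodendrocytes (7). With a minimum count of 50 the numbers were 1 in astrocytes, 1 in endothelial cells, 3 in oligodendrocyte precursors, 4 in cluster 16, 5 in excitatory neurons, 3 in microglia and 3 in newly formed oligodendrocytes. DESeq2 called 10 in mature oligodendrocytes, 4 in microglia, 9 in mural cells, 3 in newly formed oligodendrocytes and 1 for the interaction (34). Thinned cells gave 13 in inhibitory neurons, 3 in microglia, 4 in newly formed oligodendrocytes, 3 for the interaction and 601 between inhibitory and excitatory neurons (2254), where 613 were called with no library block. With doublets kept 4 were called in microglia, with stricter cells 11 in mural cells, and at resolution 2.0 there were 12 in newly formed oligodendrocytes. For all of these the cause was not tested. Genes tested in both ways also gained calls without the filter, such as Avp in inhibitory neurons (1.09 with or without it).

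Same-number libraries of the 2 sexes correlated at 0.381, 0.0805 and 0.291 after centring, and pairs with different numbers at -0.354 to 0.296. Each library was closest to its own number except female replicate 2, which was closest to male replicate 1, a hint of pairing from the data and not the design. With 1 pair under 0.1, the numbers were not taken to pair the libraries. With the number as a block, 69 genes were called in cluster 0, 1 in endothelial cells, 1327 in inhibitory neurons and 14 in oligodendrocyte precursors. Fitted without female replicate 3, cluster 16 had 51, excitatory neurons 1288 and microglia 33. In these classes, as in newly formed oligodendrocytes, number 3 held male replicate 3 alone, which its block term absorbs. Such fits rest on replicates 1 and 2, so their counts cannot be set beside the others. The block ended the calls of Gm29650 in all cells (-9.04), Ddx3y in endothelial cells (-8.27) and Gm42418 (0.97) and Rps18-ps3 (-1.12) in newly formed oligodendrocytes, and of no other gene named. Swapping the sexes within numbers 2, 3 or both gave 34, 111 and 13 in inhibitory neurons.

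Leaving out each library in turn gave 4 to 7 genes in all cells, 1 to 3 in astrocytes, 6 to 19 in cluster 0, 1 to 2 in endothelial cells, 6 to 17 in inhibitory neurons, 5 to 6 in mature oligodendrocytes, 4 to 10 in oligodendrocyte precursors, 11 to 27 in cluster 16, 5 to 16 in excitatory neurons, 3 to 64 in microglia, 2 to 27 in mural cells, 3 to 25 in newly formed oligodendrocytes, 14 to 31 for the interaction and 1605 to 2445 between inhibitory and excitatory neurons. Where it left 1 female library, that library was taken to vary like the others. Class shares and neuronal cluster sizes had 0 calls in all alternatives, though exact permutation of 3 libraries against 3 could give none. The replicate block gave cluster 16 and cluster 2 of the neurons adjusted p = 0.0576 each.

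For the listed genes across classes (0 by exact sign flips), edgeR called 47 over 6 libraries and 45 over 11 classes (41 to 51 without each library). Called lists numbered 47 in the 6-library comparisons of sex, 3 with an estimated correlation, 12 by fry and 38 to 55 without each library; 35 in the 5-library comparisons, 0, 6 and 25 to 37; 7 between inhibitory and excitatory neurons, 0 with an estimated correlation, 6 by fry and 5 to 7 without each library; and 3 for the interaction, 0, 0 and 2 to 6. An estimated correlation above the preset gives a stricter test by its construction. Thinning and stricter cells could not be run in astrocytes and endothelial cells, which then fell under 20 cells in a library, and cluster 0 and cluster 16 have no counterpart where cells were clustered anew. Of the 8 classes or sets simulated for sex, 2-fold changes were mostly missed in astrocytes and endothelial cells (18% and 24% found). Clusters 0 and 16, mural cells and newly formed oligodendrocytes were not simulated.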

Other observations

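The test in this part was chosen after the values were seen. Some mature oligodendrocytes held many UMIs of Tac1, the substance P gene, and did so more often in male libraries. Cells with at least 3 Tac1 UMIs were 0.715, 1.51 and 0.735% of mature oligodendrocytes in female replicates 1, 2 and 3 (6 of 839, 29 of 1926 and 1 of 136) and 3.83, 5.25 and 3.80% in male replicates 1, 2 and 3 (46 of 1200, 104 of 1983 and 21 of 553). The means were 0.985 ± 0.451% and 4.29 ± 0.826% (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). Measured alike over all libraries, the share was 3.12% in mature oligodendrocytes (median depth 4826 UMIs), 1.05% in endothelial cells (3674.5), 0.733% in newly formed oligodendrocytes (5604), both of which should lack the gene, 5.71% in oligodendrocyte precursors (4043.5) and 51.8% in cluster 0 (5834). The female shares lay near those of endothelial cells and newly formed oligodendrocytes and near that of microglia (1.14%), and the male shares lay above these. Oligodendrocyte precursors, which are not neurons either, lay above each male share at 5.71%. The other classes therefore do not place the male shares above background, and they were not measured by sex. No explanation was tested for this difference between the sexes.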
